A study of Mus musculus with 4 samples.

How the data were processed

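Gene expression was measured by droplet single-cell RNA sequencing (10x Genomics) of muscle stem cells sorted by GFP from Tg:Pax7-nGFP mice. There were 4 libraries, 1 each for quiescent EOM, quiescent TA, activated EOM and activated TA cells. The files deposited by the authors hold raw UMI counts per gene and cell barcode, made with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes. The annotation release behind the counts, the rule by which barcodes were called as cells, and how many animals went into each library are not given in the sources used here. No deposited cell type annotation was used.

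The files list 31055 features, of which 30934 gene IDs matched GENCODE vM21, an annotation of the GRCm38 assembly that may differ in release from the one used for counting. All 351 named genes had a position in it. The libraries' barcodes had at least 507 (quiescent EOM), 501 (quiescent TA), 512 (activated EOM) and 504 UMIs (activated TA).

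Barcodes were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrially encoded genes. In the order just given, 140, 565, 856 and 663 barcodes fell under the first limit. Scrublet, run through scanpy 1.11.5, scored each library for doublets; its automatic threshold called 1, 0, 0 and 0 doublets and so did not work. The highest-scoring barcodes were removed by rank instead, as many as 0.8% per 1000 barcodes predicts, which took out 139, 161, 433 and 274 of the barcodes that passed the other filters. Each library was then clustered on its own with scanpy and the Leiden method of igraph 0.11.9 (scaling to 10000 UMIs, log values, 2000 variable genes, 30 principal components, 15 neighbours, resolution 1). A cluster was named for a cell type when at least 3 markers of that type were 4-fold higher than in the library's other cells, at least 1 was among its top 10 genes, and the type had more such markers than muscle did; clusters named for a non-muscle type were left out. This removed 16 endothelial-like cells of quiescent TA and no cell of the other libraries. The order of filtering and clustering and these naming limits were set after a first clustering of all barcodes had been seen. The cells kept were 84.4%, 55.5%, 73.3% and 70.4% of barcodes, with 17497225, 15286796, 122868688 and 102471329 UMIs.

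UMIs were summed over the kept cells of a library and scaled to CPM by the library's total. A gene's ratio between a pair of libraries is given as a fold of CPM with an exact 95% interval for a ratio of Poisson rates, and on the log2 scale with a pseudocount of 1 CPM. A gene with no UMI in one library was set at a floor of 3 counts over that library, and its fold is a lower bound. With 1 library per group no test between groups was made; a model adding muscle and state over the 4 libraries, with 1 residual degree of freedom, was not fitted. Genes were counted by size alone, as at least 2-fold apart among genes with at least 20 CPM in either library. The 4 comparisons were EOM against TA in quiescent and in activated cells, and activated against quiescent cells in each muscle; the EOM to TA ratios of the states, and the activation ratios of the muscles, were also set against each other.

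There were 24 gene lists and 14 lists of cell type markers. Each list was summarised by the median log2 ratio of members with at least 5 CPM in either library, where at least 3 were measured, and by the percentile of that median among 10000 random lists of the same size matched on mean CPM in 20 bins. Random lists take no account of members that move together or of differences between single libraries. Their spread may thus be too narrow, and a percentile only describes these libraries. Genes named in the text were chosen by rule: per comparison the 12 largest and 12 smallest ratios among genes with at least 50 CPM in the higher library, up to 3 members per list and direction at 20 CPM or more, all members at 20 CPM or more of the myogenic, head, trunk and mesenchymal lists, the genes of the state shares, and the 8 genes per direction whose activation ratio differed most between muscles. That rule left out sex-linked genes, haemoglobins, mitochondrially encoded genes, ribosomal proteins and unnamed gene models. Some genes that the rule names are not reported here. Imprinted genes, mural and fibroblast markers, genes shared between states and genes with opposite directions were named outside the rule, after their values were seen. The cell filters, gene lists, markers, naming rule, comparisons and most alternatives were fixed before the data were examined.

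Shares of cells with a UMI of a gene were taken after thinning each cell without replacement to 2000 UMIs, with exact binomial intervals and, for a share of 0, the limit that 3 counts over the same cells give, and the share without thinning is given for the main state genes. The endothelial-like cells served as the reference for free RNA. Activated cells were also matched between muscles, after the data had been seen, in 20 bins of their share of UMIs from the differentiation list.

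The steps were tested on simulated counts drawn from the libraries' own means and totals, with 200 genes changed per comparison. The changed genes were drawn from those with a mean at least 2-fold above the 20 CPM minimum. Counts were Poisson without variation between cells or libraries, so the simulation checks the calculation and not differences between single libraries. In steps on 4987 (quiescent EOM against TA), 4941 (activated EOM against TA), 5401 (activation in EOM) and 5172 genes (activation in TA), 100% of genes changed 3-fold or 6-fold and 0% of those changed 1.5-fold were called at least 2-fold apart, as was no unchanged gene. Intervals held the true ratio for 95.4%, 94.5%, 94.7% and 95.1% of genes. Thinning of 2000 simulated cells gave a share of 87.45% where 86.8% was due.

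Alternatives were cell filters of at least 1000 genes, at most 5% mitochondrial UMIs or none; no doublet removal or 2 times as many removed; non-muscle clusters kept; scaling by TMM (edgeR 4.0.16 in R 4.3.3), by median-of-ratios factors, or by totals without mitochondrial and ribosomal protein genes; pseudocounts of 0.1 and 10 CPM; expression minimums of 5 and 100 CPM or none; each cell weighted equally; sums of cells thinned to 2000 UMIs; sums without cells holding Myog, Mymk or Mymx, or Mki67 or Top2a; and shares thinned to 1000 or 5000 UMIs or not at all. A limit of 20% mitochondrial UMIs and the same cell state settings read after thinning to 2000 UMIs were added after the data had been seen. Read without thinning, the cell state settings are more likely to leave out deep cells than shallow ones. Ratios of single genes in these settings are those read without thinning unless 2000 UMIs are named. Without Myog, Mymk or Mymx they rest on 687 activated EOM and 215 activated TA cells, and without Mki67 or Top2a on 793 and 650. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.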

Results

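Muscle stem cells, also called satellite cells, are the Pax7-expressing progenitors that lie along muscle fibres and rebuild them. They were sorted by green fluorescence from mice 2 to 4 months old that carry a nuclear GFP under Pax7 control, and their polyadenylated RNA was counted cell by cell on the 10x Genomics droplet platform. The cells came from the extraocular muscles (EOM), which move the eye, and from the tibialis anterior (TA), a muscle of the lower leg. From each muscle there was 1 library of quiescent cells, processed directly after sorting, and 1 library of activated cells, grown for 4 days on Matrigel in growth medium at 3% oxygen, so that 4 libraries made up 4 groups. No group had a replicate: differences between libraries have no replicate check, no test was made, and every interval covers counting error only.

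The libraries held 4262 barcodes and 19774384 UMIs (quiescent EOM), 5225 and 22253751 (quiescent TA), 7597 and 144188957 (activated EOM), and 6086 and 118537060 (activated TA). After filtering, 3596, 2902, 5566 and 4284 cells remained in that order, with medians of 4664, 5030, 21284 and 23364.5 UMIs per cell. A count of 3 UMIs over a whole library, the floor used for a gene with none, equalled 0.171, 0.196, 0.0244 and 0.0293 CPM, the unit in which every library is scaled to the same total of counts. Libraries differed in cell quality: 40.5% of barcodes in quiescent TA had more than 10% mitochondrial UMIs, against 11.7% in quiescent EOM, 20.9% in activated EOM and 24.7% in activated TA. The order was another one at more than 50% mitochondrial UMIs, with 16.8% of barcodes in activated EOM and 18.9% in activated TA, against 0.211% in quiescent EOM and 1.44% in quiescent TA. The cells kept had median mitochondrial shares of 6.93% (quiescent EOM), 7.90% (quiescent TA), 6.23% (activated EOM) and 6.24% (activated TA). Y-linked genes were counted in all 4 libraries and Xist gave at most 9 UMIs in the kept cells of any library and at most 13 over all its barcodes. The GFP transgene transcript was at 24.6, 24.3, 19.2 and 17.8 CPM in the same order as above.

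The state genes set quiescent and activated cells apart in the same way in both muscles. In cells thinned to 2000 UMIs, a UMI of Myog, Mymk or Mymx, which drive terminal differentiation and myoblast fusion, was present in 0.199% (Clopper-Pearson 95% interval 0.0801 to 0.410) of quiescent EOM cells and 0.176% (0.0571 to 0.410) of quiescent TA cells, against 53.2% of activated EOM and 65.2% of activated TA cells. Top2a, a topoisomerase of dividing cells, was detected in 0.768% and 0.668% of quiescent EOM and TA cells, and in 37.1% and 35.8% of activated ones. Mki67, a proliferation antigen, was found in 0.626%, 0.738%, 25.5% and 22.3%. Pax7 was detected in 38.7% of quiescent EOM and 48.2% of quiescent TA cells, and Myf5, a determination factor, in 34.1% and 38.0%. Thinning left out 82, 57, 31 and 47 cells below 2000 UMIs. Without thinning, the share with Myog, Mymk or Mymx was 0.334%, 0.241%, 87.7% and 94.98%, and Pax7 was found in 61.5%, 72.6%, 57.0% and 52.7%, at the unequal depths given above.

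As a reference for free RNA, 16 endothelial-like cells of the quiescent TA library, 13 of them at 2000 UMIs or more and with a median of 7804 UMIs against 5067 in that library's muscle cells, gave Pax7 and Myf5 in 15.4% each (1.92 to 45.4) and Myod1 in 38.5% (13.9 to 68.4). Myog, Mymk, Mki67, Pdgfra and Pdgfrb were in 0 of these 13 cells, which allows a share of up to 23.1% as 3 counts of 13 (exact upper bound 24.7). In that library's muscle cells Pax7 (48.2%) lay above the interval of the reference, while Myf5 (38.0%) and Myod1 (46.1%) lay within theirs. Doublets of endothelial and muscle cells missed by the removal by rank would raise the reference's shares too, which was not tested. No named cluster of this kind was found in the other 3 libraries, so the free RNA behind their shares was not measured. Pax7 was detected in 13.1% of activated EOM and 9.39% of activated TA cells, Myf5 in 9.11% of activated EOM cells and Myod1 in 12.1% of quiescent EOM cells. These shares lay below the reference's, but a reference from quiescent TA cannot measure free RNA in other libraries. Neither expression nor its absence is read from these shares alone. Pax7 was at 75.4 and 55.1 CPM in activated EOM and TA. Myod1 was detected in 54.0% of activated EOM and 80.6% of activated TA cells.

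The first comparison asks how quiescent stem cells of an eye muscle differ from those of a limb muscle. Transcription factors of the trunk and limb programme were far lower in EOM cells, and factors of the head and eye-muscle programme were higher. Matrix glycoproteins and proteoglycans and interferon response genes were higher in EOM as lists, while cholesterol synthesis genes, Mt1 and Myod1 were lower. Of 5425 genes at 20 CPM or more in either library, 154 were at least 2-fold higher and 136 at least 2-fold lower in EOM (53.1% higher); with edgeR's TMM factors these were 106 and 165 (39.1% higher), and with median-of-ratios factors 109 and 173 (38.7% higher). Over all these genes the median log2 ratio was 0.06, and -0.08 with TMM.

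Among the trunk and limb regulators, 12 of 14 measured members were at least 2-fold lower in quiescent EOM and 2 were higher. 8 Hox genes had no UMI in EOM. Hoxc10 (chromosome 15, 102966796 to 102971893, plus strand, GENCODE vM21 on GRCm38) was at 81.6 CPM in TA and at least 476-fold lower in EOM, and Hoxc9 and Hoxa10 were at least 174-fold and 88.9-fold lower. Lbx1, a homeobox gene of migrating limb muscle precursors, gave 0.0572 CPM in EOM and 29.2 in TA (0.00195 times, 4.94e-05 to 0.0109), and Pax3, which marks trunk and limb muscle progenitors, 0.114 and 13.3. The list's median log2 ratio was -3.35, or -5.40 with the 8 genes without a UMI at their bound, at percentile 0 of 10000 matched random lists. Vgll2, a cofactor of TEAD factors in muscle (chromosome 10, 52022502 to 52028471), stood outside the list at 9.26 against 215 CPM (0.0431 times, 0.0366 to 0.0505).

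Head and eye-muscle regulators went the other way, with 7 of 11 measured members at least 2-fold higher in EOM and 3 lower (median 1.54, percentile 100). Foxc1, a forkhead factor (chromosome 13, 31806633 to 31812476), was 35.9-fold higher (23.1 to 59.1), Dmrta2, a doublesex-related factor, 117-fold (53.6 to 320), and Barx2, a homeobox factor, 22.1-fold (16.7 to 29.9). Outside this list, the Iroquois factor Irx5 was 65.3-fold (37.2 to 127) higher, and so was Eya2, a transcriptional coactivator of the myogenic list (26.3-fold, 17.4 to 41.8). Msc, or musculin, was the abundant exception, at 78.0 CPM in EOM and 296 in TA (0.264 times, 0.248 to 0.280). Mesenchymal transcription factors had 10 of 31 members at least 2-fold higher and 2 lower (median 0.39, percentile 99.95). This list and the preceding pair hold factors that the study may have been built around, so their direction is not independent evidence.

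**Figure D1:**
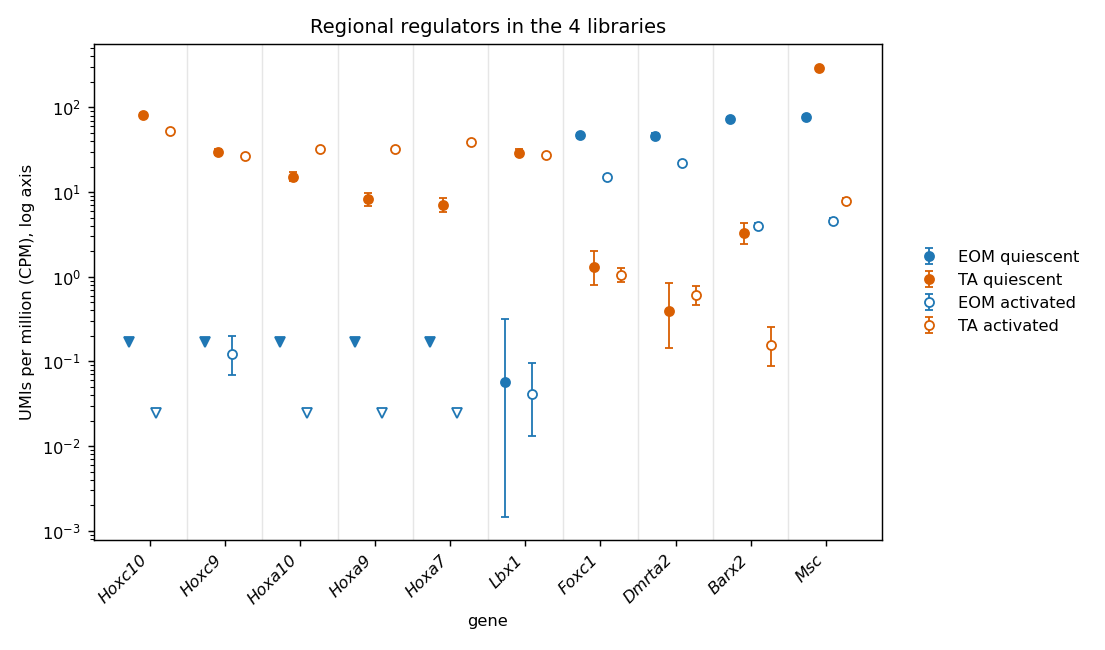
Expression of 10 positional and head regulators in the 4 libraries, on a log axis in CPM, with 95% Poisson intervals as bars and triangles for genes with no UMI, placed at the 3-count floor of that library. Hoxc10, Hoxa10, Hoxa9 and Hoxa7 had no UMI in either EOM library, while Foxc1 and Dmrta2 were above 15 CPM in both EOM libraries and at 1.31 CPM or less in both TA libraries.

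Myogenic regulatory factors had 2 of 17 members at least 2-fold higher and 3 lower in quiescent EOM (median -0.35, percentile 0.02). Myod1, a determination factor (chromosome 7, 46376474 to 46379099), was at 151 CPM in EOM and 1197 in TA (0.126 times, 0.121 to 0.131). Pax7 was 0.741 times (0.713 to 0.769) and Myf5 0.764 times (0.734 to 0.795) the TA level. Quiescent satellite cell genes as a list lay higher in EOM (median 0.25, percentile 99.97, 3 of 29 at least 2-fold higher and 1 lower). Chrdl2, a BMP antagonist, was 2.33-fold higher (2.24 to 2.42) and Cd34, a surface sialomucin, 1.93-fold (1.81 to 2.06), and Asb5 was lower at 0.322 times (0.316 to 0.328). Differentiation genes (12 measured) had a median of 0.12 at percentile 67.8, which was -0.01 with TMM. S phase genes (24 measured) had 0.32 at percentile 96.9, and G2 and M phase genes (18 measured) 0.15 at percentile 70.7.

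Matrix glycoproteins and proteoglycans were higher in quiescent EOM, with 12 of 49 members at least 2-fold higher and 4 lower (median 0.44, percentile 100). The elastic fibre genes Mfap4 and Fbln5 were 18.1-fold (13.5 to 24.8) and 12.6-fold (10.3 to 15.6) higher, and the proteoglycan genes Vcan and Bgn 7.04-fold (5.83 to 8.56) and 4.36-fold (4.08 to 4.66). Thbs1, encoding thrombospondin, was 0.195 times the TA level (0.163 to 0.232). Matrix enzymes had 2 of 33 members at least 2-fold higher and 4 lower (median 0.24, percentile 99.6). Collagens split, with 5 of 19 higher and 2 lower and a median of 0.03 (percentile 26.3) that was -0.09 with TMM and -0.10 with median-of-ratios factors. Col1a2, a chain of type I collagen (chromosome 6, 4504814 to 4541544), was 2.59-fold higher in EOM (2.32 to 2.89), a log2 ratio of 1.34 that was 0.43 when cells with up to 20% mitochondrial UMIs were kept and -1.08 with at most 5%, where 46 TA cells were left. Col1a1, its partner chain, was 0.498 times the TA level (0.372 to 0.664), a log2 ratio of -0.86 that was -2.85 with up to 20%. Marker genes of mural or smooth muscle cells had 2 of 7 at least 2-fold higher in EOM and 0 lower (median 0.72, percentile 99), while fibroblast markers split, with 1 of 7 at least 2-fold higher and 1 lower (median -0.27, percentile 2.12); Dcn was at 38.6 CPM in EOM and 24.1 in TA.

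Cholesterol synthesis genes were lower in quiescent EOM, with 11 of 21 members at least 2-fold lower and 0 higher (median -1.06, percentile 0). Fdps, farnesyl diphosphate synthase, was 0.269 times (0.244 to 0.297) and Msmo1, a methylsterol oxidase, 0.282 times (0.259 to 0.306) the TA level. Of 39 antioxidant genes 0 were at least 2-fold higher and 6 lower (median -0.05, percentile 5.04). They included the metallothionein Mt1 at 2882 against 13664 CPM (0.211 times, 0.209 to 0.213) and heme oxygenase Hmox1 (0.145 times, 0.137 to 0.152). These genes were lower in the library with the lower median mitochondrial share. Ahr, the aryl hydrocarbon receptor, was 0.0513 times (0.0388 to 0.0667), Pcdh17, a protocadherin, 0.135 times (0.117 to 0.154), and Ptx3, a secreted pentraxin, 0.266 times (0.234 to 0.301).

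Interferon response genes were higher in quiescent EOM, with 6 of 26 members at least 2-fold higher and 0 lower (median 0.50, percentile 100). The chemokine Cxcl10 stood outside that list and was 6.61-fold higher (6.15 to 7.10); in the list, the factor Irf1 was 4.19-fold (3.89 to 4.51) and Ifit1 3.87-fold (3.43 to 4.37) higher. H19, an imprinted non-coding RNA, was 6.48-fold higher (5.66 to 7.45), Bex1 6.71-fold (5.68 to 7.97), Lbp, a lipopolysaccharide-binding protein, 5.51-fold (4.67 to 6.53), and Tshr, the thyrotropin receptor, 4.91-fold (4.45 to 5.43). Tac4, a tachykinin precursor, was 4.89-fold (4.27 to 5.63) and Islr 4.55-fold higher (4.17 to 4.98).

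The remaining lists moved little between quiescent muscles. Immediate early and stress genes, which respond within minutes to handling, had a median of -0.04 over 49 (percentile 17.2), although Fos (1.42-fold, 1.40 to 1.44) and Fosb (1.65-fold, 1.62 to 1.67) were higher in EOM. Notch pathway genes had 0.20 over 17 (percentile 87.4), Wnt, BMP and TGF-beta genes 0.23 over 27 (percentile 96.5) and growth factors and receptors -0.07 over 39 (percentile 1.90). Medians were -0.00 for glycolysis (18 genes, percentile 27.4), 0.03 for the hypoxia response (22, percentile 27.3), 0.08 for ribosomal proteins (77, percentile 98.0) and 0.04 for nuclear respiratory chain genes (88, percentile 64.9); with TMM the last 3 turned to -0.09, -0.05 and -0.08. Mitochondrially encoded respiratory genes were at -0.20 over 13 (percentile 1.79) and the sex-linked genes at -0.04 over 4 (percentile 29.2).

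In activated cells the comparison asks which muscle differences are seen after 4 days of growth outside the animal. Matrix genes stood out: collagens, matrix glycoproteins and matrix enzymes were all higher in EOM cells as lists. The 3 together had a median log2 ratio of 0.47, which was 0.27 in cells matched on their share of differentiation UMIs. It was 0.56 in cells without Myog, Mymk or Mymx at 2000 UMIs. Differentiation genes had a slightly lower median, with Acta1 and Tnnt2 lower and Actc1 higher. Positional regulators were again far apart between the muscles. Of 5297 genes at 20 CPM or more, 103 were at least 2-fold higher and 48 at least 2-fold lower in EOM (68.2% higher, and 67.7% with TMM), fewer than in quiescent cells.

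Collagens had 8 of 17 members at least 2-fold higher in activated EOM and 3 lower (median 0.71, percentile 100). Col1a2 was at 543 CPM in EOM and 75.7 in TA (7.18-fold, 7.01 to 7.35), and the type VI chains Col6a1 and Col6a2 were 13.8-fold (12.1 to 15.8) and 16.5-fold (12.7 to 21.9) higher. Glycoproteins and proteoglycans had 9 of 35 higher and 2 lower (median 0.50, percentile 100), led by Mgp, matrix Gla protein (chromosome 6, 136872435 to 136875823), at 278 against 13.4 CPM (20.7-fold, 19.6 to 21.9), and by Bgn at 6.57-fold (6.30 to 6.85). Matrix enzymes had 5 of 30 higher and 0 lower (median 0.40, percentile 100), among them the gelatinase Mmp2 (12-fold, 10.3 to 13.9) and the procollagen enhancer Pcolce (3.34-fold, 3.17 to 3.52). Islr was 8.68-fold higher (8.21 to 9.18). Pdgfrb, a PDGF receptor also made by mural cells, was at 30.7 against 1.07 CPM (28.6-fold, 23.6 to 34.8), a log2 ratio of 3.93 that was 2.15 in cells without Mki67 or Top2a; over the same change of cells Bgn went from 2.67 to 1.75, Pcolce from 1.69 to 0.59 and Mmp2 from 3.03 to 2.43. Without cells holding Myog, Mymk or Mymx (687 EOM and 215 TA cells left), Mgp went from 4.27 to 3.28 and Col6a1 from 3.30 to 2.5.

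Markers of other cell types were looked at beside these genes. Mural or smooth muscle markers split in activated EOM, with 2 of 5 at least 2-fold higher, Pdgfrb among them, and 1 lower (median 0.78, percentile 99.97). Fibroblast markers had 1 of 6 at least 2-fold higher and 1 lower (median 0.34, percentile 99.7). Of the fibroblast genes, Col1a1 was at 11.2 CPM in activated EOM and 2.80 in activated TA, and Col3a1 at 67.4 and 55.1. Dcn and Dpt were at 0.0163 CPM in activated EOM and 0.0195 in activated TA, from 2 UMIs each. Pdgfra was detected at 2000 UMIs in 0.0181% of activated EOM cells and 0 of 4237 activated TA cells. The latter allows up to 0.0708% of cells with a UMI at that depth and sets no limit on cells that express Pdgfra. Without thinning it was found in 0.216% (12 cells) of activated EOM and 0.35% (15 cells) of activated TA, so no order is read from these shares. Differentiating muscle markers had a median of -0.23 over 17 (percentile 0), fibre markers 0.26 over 6 (percentile 98.4) and muscle stem cell markers -0.02 over 12 (percentile 45.6). In quiescent cells the stem cell markers were at 0.08 over 15 (percentile 80.5), differentiating markers at -0.06 over 3 (percentile 22.7), fibre markers at -0.33 over 3 (percentile 5.43), glial markers at 0.26 over 3 (percentile 54.8) and immune markers at 0.21 over 3 (percentile 48.1). Tenocyte, endothelial, red blood cell, epithelial, pigment, neuronal and cartilage or bone markers had at most 2 measured members in either comparison of muscles and gave no median, as did glial and immune markers in activated cells.

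**Figure D2:**
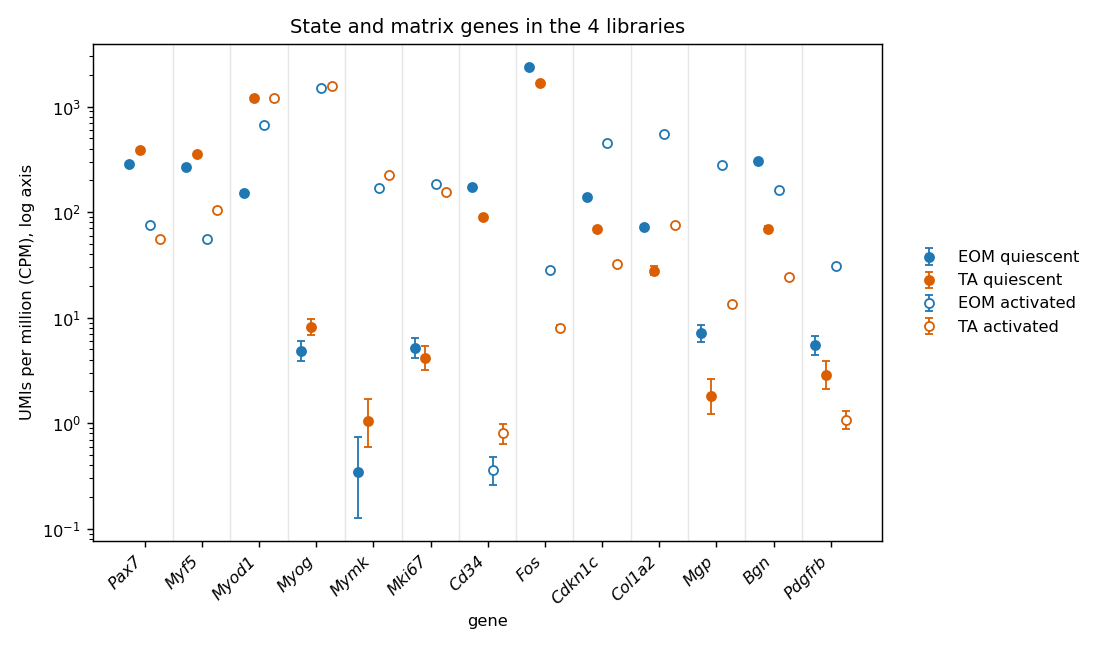
Expression of 13 state, matrix and growth genes in the 4 libraries, on a log axis in CPM, with 95% Poisson intervals as bars. Myog and Mymk were above 150 CPM in both activated libraries and at 8.18 CPM or less in both quiescent ones, and Col1a2, Mgp and Cdkn1c were highest in activated EOM.

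Contractile and differentiation genes had a slightly lower median in activated EOM, with 2 of 40 at least 2-fold higher and 4 lower (median -0.15, percentile 0). The median was 0.04 in cells without Mki67 or Top2a, read without thinning. It was -0.62 in cells without Myog, Mymk or Mymx at 2000 UMIs (2626 EOM and 1458 TA cells left). Skeletal actin Acta1 (chromosome 8, 123891769 to 123894751) was at 1186 against 3301 CPM (0.359 times, 0.357 to 0.362) and troponin T2, Tnnt2, at 0.384 times (0.379 to 0.389). The log2 ratios of Acta1 and Tnnt2 were -1.48 and -1.38. Read without thinning, they were -0.84 and -0.68 in cells without Mki67 or Top2a (793 EOM and 650 TA cells left). Without Myog, Mymk or Mymx they were -3.32 and -4.50, from the 687 EOM and 215 TA cells left. Cardiac actin Actc1 was higher in EOM at 1003 against 346 CPM (2.89-fold, 2.86 to 2.93). Myogenic factors had 1 of 17 at least 2-fold higher and 0 lower (median -0.07, percentile 14.4). Myod1 was 0.555 times (0.550 to 0.560), Myf5 0.528 times (0.512 to 0.544), Pax7 1.37-fold (1.32 to 1.41) and Myog 0.956 times (0.949 to 0.962) the TA level. The log2 ratio of Myod1, -0.85, was -0.18 in the same cells without Mki67 or Top2a and -1.87 in the same cells without Myog, Mymk or Mymx.

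As lists, regulators of position lay on the same sides in activated cells, though not every member did. Trunk and limb regulators had 10 of 12 members at least 2-fold lower in EOM and 0 higher (median -4.49, or -8.75 with 7 genes at their bound, percentile 0), with Hoxc10 at least 2163-fold and Hoxa7 at least 1610-fold lower. Head and eye-muscle regulators had 6 of 9 higher and 1 lower (median 1.38, percentile 100). Foxc1 was 14.3-fold (11.8 to 17.5) and Dmrta2 36.6-fold (28.5 to 47.9) higher, and Irx5, outside the list, 15.7-fold (13.4 to 18.4). Mesenchymal factors had 12 of 31 higher and 0 lower (median 0.68, percentile 100), among them Creb3l1, a factor of secretory and collagen genes (2.46-fold, 2.38 to 2.55), and Nr2f2 (2.36-fold, 2.22 to 2.5). The log2 ratio of Creb3l1, 1.28, was 0.58 in cells without Mki67 or Top2a.

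The cyclin-dependent kinase inhibitor Cdkn1c, or p57 (chromosome 7, 143458339 to 143461050), was at 452 CPM in activated EOM and 32.5 in activated TA (13.9-fold, 13.4 to 14.4), a log2 ratio of 3.76 that was 2.79 in cells without Myog, Mymk or Mymx. Igfbp2, an IGF-binding protein, was 5.58-fold (5.36 to 5.82), cyclin Ccnd2 3.83-fold (3.68 to 3.98) and the imprinted gene Mest 3.57-fold (3.50 to 3.64) higher. Fabp7, a fatty acid binding protein, was 4.36-fold (4.10 to 4.64), Pmp22, a membrane protein of myelin, 5.14-fold (4.83 to 5.47), Tm4sf1 4.24-fold (4.01 to 4.49) and Capn6 3.86-fold higher (3.69 to 4.04). On the lower side were the peptide hormone gene Sct (0.214 times, 0.210 to 0.217), the tubulin Tubb3 (0.156 times, 0.147 to 0.165), Vgll2 (0.261 times, 0.248 to 0.275), Thbs1 (0.289 times, 0.282 to 0.297), Lpar1 (0.345 times, 0.329 to 0.362) and Arl4c (0.336 times, 0.323 to 0.35). In the 687 EOM and 215 TA cells without Myog, Mymk or Mymx the log2 ratio of Sct went from -2.22 to -3.38. That of Tm4sf1 went from 2.01 to 1.27 and that of Pmp22 from 2.26 to 2.91.

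Signalling lists were mostly higher in activated EOM. Wnt, BMP and TGF-beta genes had 6 of 24 at least 2-fold higher and 0 lower (median 0.35, percentile 100). Notch pathway genes had 3 of 15 higher and 0 lower (median 0.19, percentile 99.1), with Notch3 at 2.73-fold (2.55 to 2.92) and Hey1 at 2.73-fold (2.53 to 2.95). The Notch median was -0.17 in cells without Mki67 or Top2a, read without thinning (793 EOM and 650 TA cells left). It kept its sign with that setting at 2000 UMIs (2851 and 2281 cells left). Immediate early genes had 6 of 42 higher and 0 lower (median 0.06, percentile 97.0, and -0.01 with median-of-ratios factors), with Fos 3.57-fold (3.31 to 3.85) and Egr1 3.66-fold (3.49 to 3.84) higher. In cells without Mki67 or Top2a the log2 ratios of Hey1, Fos and Egr1, 1.35, 1.71 and 1.82, were 0.67, 0.87 and 1.08. Quiescent satellite cell genes had 5 of 22 higher and 1 lower (median 0.30, percentile 100), and hypoxia genes 1 of 21 higher (median 0.36, percentile 100). Cholesterol genes were lower again, with 0 of 22 higher and 1 lower at 2-fold (median -0.43, percentile 0).

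Other activated medians were small: growth factors 0.08 over 30 (percentile 96.1), glycolysis 0.14 over 20 (percentile 99.9), nuclear respiratory genes 0.09 over 90 (percentile 100), and the sex-linked genes -0.07 over 4 (percentile 26.4). Medians near 0 that turned sign with median-of-ratios factors were those of S phase (0.02 over 44, percentile 88.6), G2 and M phase (0.05 over 54, percentile 98.8), antioxidant genes (0.02 over 34, percentile 81.9), ribosomal proteins (0.03 over 77, percentile 96.9) and mitochondrially encoded genes (0.01 over 13, percentile 64.7). The interferon list, at -0.10 over 9 (percentile 11.0), turned to 0.23 when totals left out mitochondrial and ribosomal genes.

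**Figure D3:**
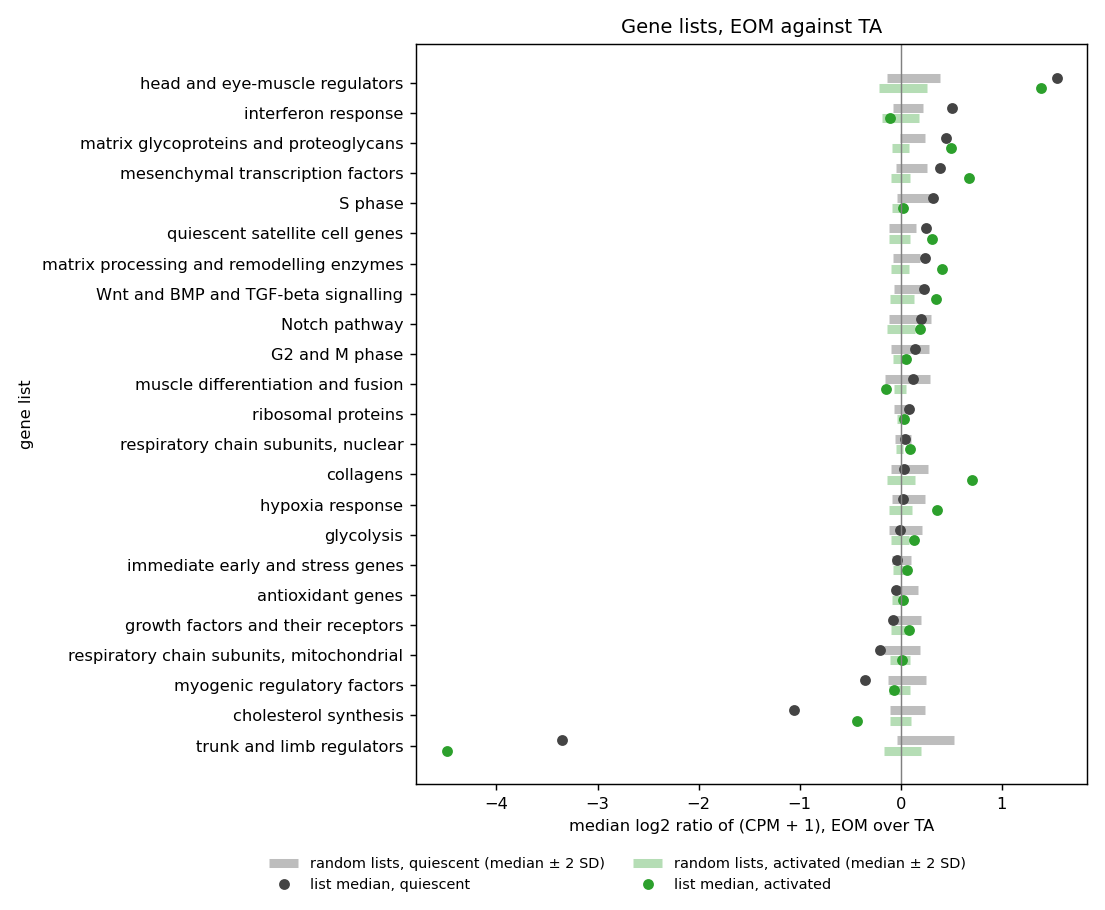
Median log2 ratio of EOM over TA for 23 gene lists, grey points for quiescent and green points for activated cells, with bands at the median of random matched lists plus and minus 2 of their standard deviations. Trunk and limb regulators lie far to the left and head and eye-muscle regulators far to the right in both states, cholesterol genes lie to the left in both, and collagens lie apart from their band in activated cells.

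Growth for 4 days was compared with the quiescent state within each muscle, the question being what activation brings in either muscle. The cell cycle and contractile programmes were higher in activated cells of both muscles, and genes of quiescent satellite cells, immediate early genes and interferon genes were lower. Quiescent cells were processed directly after sorting and activated cells after 4 days in culture, so activation cannot be told apart from handling or culture. This bears most on the immediate early genes, which respond within minutes to handling. In EOM 1732 of 6423 genes were at least 2-fold higher and 1542 lower (52.9% higher), and in TA 1884 of 6302 higher and 1527 lower (55.2%). TMM factors moved these splits to 2488 and 1092 in EOM (69.5% higher) and to 2411 and 1253 in TA (65.8%), and the median log2 ratio of all genes from 0.14 to 0.62 and from 0.21 to 0.56. Median-of-ratios factors gave 62.9% and 61.6% higher. The activated libraries also had more than 4 times the UMIs per cell.

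Differentiation and fusion genes had 36 of 40 members at least 2-fold higher and 0 lower in both muscles, with medians of 5.10 in EOM (5.95 with genes without a UMI at their bound) and 5.22 in TA (5.28 at the bound), both at percentile 100. Myog was at 4.86 CPM in quiescent and 1483 in activated EOM (305-fold, 247 to 382), and at 8.18 and 1552 in TA (190-fold, 159 to 228). Mymx, the fusion micropeptide gene also called myomixer, had no UMI in quiescent cells and was at least 1292-fold higher in activated EOM and at least 622-fold in activated TA. Acta1 was 1730-fold (990 to 3347) higher in EOM and 1484-fold (1062 to 2143) in TA, and the myosin light chain Mylpf 1318-fold (844 to 2190) and 2568-fold (1604 to 4409). Embryonic myosin Myh3 was 2194-fold higher (607 to 18113) in EOM and at least 1873-fold in TA. Titin, Ttn, was 1396-fold and 1109-fold higher, and the matrix gene Spp1, osteopontin, was at least 1143-fold and 1388-fold higher.

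Genes of dividing cells followed. S phase genes had 41 of 44 members at least 2-fold higher in EOM and 42 of 44 in TA (medians 2.89 and 3.14), and G2 and M phase genes 49 of 54 and 49 of 53 (medians 4.65 and 4.63), with 0 lower in any of these and all at percentile 100. Cdk1, the mitotic kinase, was 380-fold (237 to 652) and 447-fold (256 to 866) higher, Birc5, survivin, 565-fold (323 to 1093) and 224-fold (152 to 346), and Ube2c 411-fold (266 to 673) and 320-fold (213 to 504). Nuclear respiratory chain genes had 61 of 91 and 57 of 89 at least 2-fold higher with 1 lower in each (medians 1.25 and 1.17, percentile 100). Glycolysis genes had 12 of 21 higher in both muscles, with 2 lower in EOM and 3 in TA (medians 1.95, percentile 100, and 1.51, percentile 99.99), among them Pgk1, phosphoglycerate kinase, at 14.0-fold (13.3 to 14.6) and 12.1-fold (11.5 to 12.8). Hypoxia genes had 7 of 25 at least 2-fold higher and 11 lower in EOM (median -0.30, percentile 12.6, and 0.02 in cells without Myog, Mymk or Mymx), and 6 of 25 higher and 12 lower in TA (median -0.86, percentile 0.440).

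Quiescent satellite cell genes had 23 of 29 members at least 2-fold lower in EOM and 24 of 29 in TA, with 1 higher in each (medians -2.63 and -2.88, percentile 0). Calcr, the calcitonin receptor that marks quiescence, was 0.00238 times the quiescent level in both muscles (0.00143 to 0.00373 and 0.00126 to 0.00410). Chodl, chondrolectin, was 0.000122 times in EOM (6.96e-05 to 0.000198) and 0.000157 times in TA (8.98e-05 to 0.000255), and Cd34 0.00209 and 0.00899 times. Outside that list, Nppc, C-type natriuretic peptide, was at 1185 CPM in quiescent and 0.326 in activated EOM, and at 890 and 0.137 in TA. Apoe was 0.00135 and 0.00232 times, Timp3, a metalloprotease inhibitor, 0.00303 and 0.00227 times, Tnfaip6 0.000136 and 3.22e-05 times, and Serping1, the C1 inhibitor, 0.00238 and 0.00201 times the quiescent level. In the list, Pax7 was 0.263 times (0.254 to 0.272) in EOM and 0.143 times (0.137 to 0.148) in TA; these log2 ratios, -1.91 and -2.79, were -4.13 and -4.53 in cells without Mki67 or Top2a.

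Immediate early and stress genes had 39 of 50 members at least 2-fold lower in each muscle, with 2 higher in EOM and 3 in TA (medians -3.95 and -3.75, percentile 0); Fos was 0.0121 and 0.00481 times and Atf3 0.00189 and 0.00740 times the quiescent level. Interferon genes had 25 of 26 lower in EOM and 23 of 24 in TA, with 0 and 1 higher (medians -4.28 and -3.73, percentile 0). Growth factors and receptors had 26 of 39 lower in EOM and 28 of 41 in TA, with 7 higher in each (medians -2.17 and -2.66, percentile 0). Notch genes had 11 of 19 and 11 of 18 lower and 3 and 4 higher (medians -1.29, percentile 0.3, and -1.61, percentile 0.020), and Wnt, BMP and TGF-beta genes 16 of 30 and 16 of 28 lower and 5 and 2 higher (medians -1.15 and -1.13, percentile 0.020 in both).

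Matrix genes were mixed. Glycoproteins and proteoglycans had 10 of 50 at least 2-fold higher and 25 lower in EOM, and 10 of 47 and 26 in TA (medians -1.02 and -1.48, percentile 0), and enzymes 7 and 16 of 35 in EOM and 7 and 20 of 35 in TA (medians -0.99, percentile 0.010, and -1.42, percentile 0). Collagens had 5 higher and 8 lower of 18 in EOM (median -0.63, percentile 4.15, but 0.10 with TMM) and 3 and 10 of 19 in TA (median -1.37, percentile 0.130). Col1a2 was 7.54-fold higher in activated EOM (7.13 to 7.98) and 2.72-fold in TA (2.46 to 3.00), the latter a log2 ratio of 1.41 that was 0.52 with cells of up to 20% mitochondrial UMIs; Mgp was 39.3-fold (32.9 to 47.2) and 7.34-fold (5.06 to 11.1) higher. Dpt, dermatopontin, was 8.07e-05 times (9.76e-06 to 0.000292) in EOM and 8.00e-05 times (9.69e-06 to 0.000289) in TA.

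The other lists gave these medians for EOM and TA: myogenic factors 0.68 (percentile 88.3) and 0.35 (percentile 57.7), which were -0.57 and -0.73 in cells without Myog, Mymk or Mymx; mesenchymal factors -0.38 (percentile 7.75, and -0.00 with TMM) and -0.66 (percentile 0.755), and head and eye-muscle regulators -1.58 (percentile 1.01) and -1.70 (percentile 2.36). Trunk and limb regulators had 2 measured members in EOM and a median of -0.04 in TA (percentile 38.0, and 0.24 with TMM). Cholesterol genes were at -0.08 (percentile 39.5, and 0.31 with TMM) in EOM and -0.95 (percentile 0.190) in TA, and antioxidant genes at -0.01 (percentile 20.5) and -0.09 (percentile 9.83), which TMM turned to 0.41 and 0.18. Ribosomal proteins were at -0.01 (percentile 1.92) and 0.09 (percentile 6.38), the first of which was 0.39 with TMM, and mitochondrially encoded genes at -0.07 (percentile 16.2) and -0.28 (percentile 8.59), 0.32 and 0.01 with TMM. Among marker lists, muscle stem cell markers were at -1.91 (percentile 0) and -1.74 (percentile 0.040), differentiating markers at 7.80 and 7.40 (percentile 100), fibre markers at 1.69 (percentile 99.2) and 1.58 (percentile 98.7), fibroblast markers at -1.55 (percentile 0.600) and -2.74 (percentile 0.010), and mural markers at 0.57 (percentile 78.1) and -0.48 (percentile 22.2). Endothelial markers were at -1.30 (percentile 27.0) in EOM, and glial and cartilage or bone markers at -3.08 (percentile 0.090) and -2.89 (percentile 0.715) in TA. The sex-linked genes were at -0.84 (percentile 13.9) and -1.02 (percentile 8.08).

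**Figure D4:**
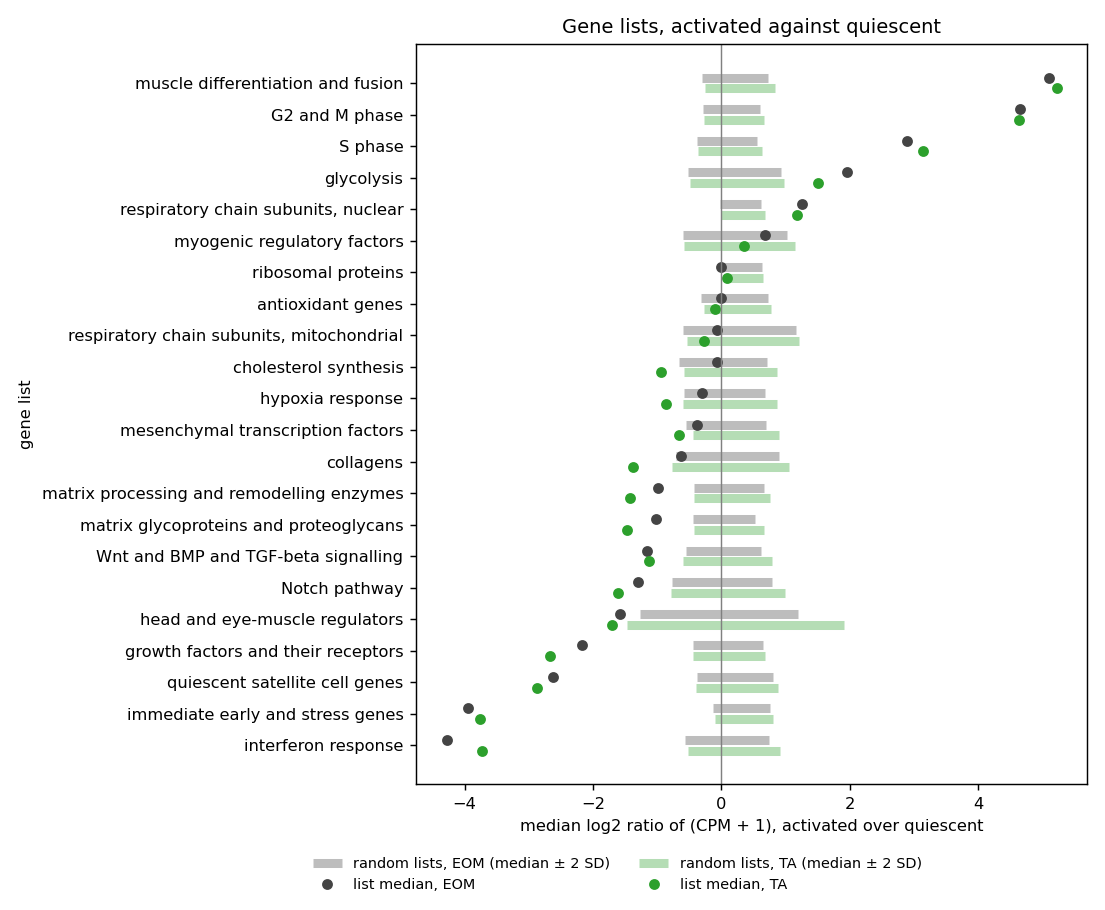
Median log2 ratio of activated over quiescent cells for gene lists, grey points for EOM and green points for TA, with bands at the median of random matched lists plus and minus 2 of their standard deviations. Differentiation, S phase and G2 and M phase lists lie to the right in both muscles, and quiescent satellite cell, immediate early and interferon lists to the left.

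The last comparison set the difference between muscles in quiescent cells beside that in activated cells. Across 6709 genes at 20 CPM or more in any library the EOM to TA ratios of the 2 states correlated weakly (Pearson r 0.35, Spearman rho 0.25, across genes, which are not independent replicates). At least 2-fold higher in EOM in both states were 31 genes, where independent lists would share 4.53, and 19 were lower in both, where independent lists would share 1.38. The shared genes included the regulators Foxc1, Dmrta2, Irx5, Barx2 and Eya2, the matrix genes Bgn, Col1a2, Col6a2, Mgp, Mfap4 and Islr, and, on the lower side, Hoxa7, Hoxa9, Hoxa10, Hoxc9, Hoxc10, Lbx1, Vgll2 and Thbs1. In quiescent cells Col1a2 fell under 2-fold with up to 20% mitochondrial UMIs (log2 ratio 0.43), and with at most 5% Col1a2 was at -1.08 and Col6a2 at -0.0809. 9 genes were at least 2-fold apart in opposite directions in the 2 states.

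Activation ratios were close between muscles, with a Pearson r of 0.96 and a Spearman rho of 0.96 across the same genes. Of 1794 genes at least 2-fold higher in EOM and 1945 in TA, 1645 were shared, where independent lists would share 520, and of 1601 and 1663 lower genes 1474 were shared, against 397. Activation ratios were at least 2-fold apart between muscles for 446 genes. Cdkn1c was 3.28-fold higher (3.15 to 3.42) in activated EOM and 0.474 times (0.442 to 0.509) the quiescent level in activated TA. In EOM its log2 ratio of 1.71 was -1.38 in cells without Myog, Mymk or Mymx (-1.27 at 2000 UMIs) and -0.00532 in cells with at most 5% mitochondrial UMIs. Lgals3, galectin 3, was 425-fold (292 to 645) and 21.5-fold (19.7 to 23.4) higher, and Mmp2 0.177 times (0.168 to 0.188) in EOM and 0.0198 times (0.0170 to 0.0230) in TA. Tendon factor Scx was 5.49-fold (4.89 to 6.18) higher in EOM and 37.7-fold (30 to 48.2) in TA, and Hes6, a bHLH factor, 19.3-fold (17.5 to 21.3) and 93.5-fold (79.3 to 111). Without cells holding Myog, Mymk or Mymx, 687 activated EOM and 215 activated TA cells were left. There the log2 ratios of Scx went from 2.39 to 0.23 in EOM and from 4.97 to 3.71 in TA. Those of Hes6 went from 4.21 to 2.45 and from 6.40 to 5.42.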

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

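The test of whether a minority of cells carried the matrix genes was set out before its result was seen, and the other tests in this part were chosen only after the results they measure, or related ones, had been seen. The 12 genes described next moved in opposite directions in groups that share a contrast; these differences were not tested, since each group is 1 library.

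For 9 genes the ratio of EOM to TA was at least 2-fold in opposite directions in quiescent and activated cells, on the log2 scale with a pseudocount of 1 CPM. They had 20 CPM or more in any of the 4 libraries, but only Ptx3 and F2r reached it in both states. In quiescent EOM and TA, Trp53i11 was at 3.03 and 0.981 CPM (53 and 15 UMIs, fold interval 1.71 to 5.90). In activated EOM and TA, Ahr was at 7.67 and 0.888 CPM. Ahr was 0.0513 times the TA level in quiescent and 8.64-fold higher in activated EOM, so that its log2 activation ratio in EOM exceeded that in TA by 6.13. For Ptx3 (0.266 times quiescent, 8.46-fold activated) that difference was 4.57, for Nrp1, a neuropilin receptor (0.215 times and 3.85-fold), 3.77, and for Col5a3 (0.363 times and 3.55-fold) 3.03. For Actc1 (0.0794 times and 2.89-fold, from 3 UMIs in quiescent EOM) it was 2.96, for Nid1, a basement membrane protein (0.409 times and 2.81-fold), 2.55, for the protease Prss23 (0.427 times and 2.25-fold) 2.19, and for the thrombin receptor F2r (0.486 times and 2.08-fold) 2.06. Trp53i11 went the other way, 3.09-fold higher in quiescent and 0.256 times the TA level in activated EOM, with a difference of -2.89.

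For 3 genes activation went up in EOM and down in TA by at least 2-fold each on that scale. Cd109 was 6.88-fold higher in activated EOM and 0.320 times the quiescent level in activated TA (difference 3.79), Cdkn1c 3.28-fold and 0.474 times (2.76), and Arhgdib 2.28-fold and 0.414 times (2.25). The log2 activation ratio of Cdkn1c in EOM, 1.71, was -1.38 in cells without Myog, Mymk or Mymx (-1.27 at 2000 UMIs) and -0.00532 with at most 5% mitochondrial UMIs, so its direction there rests on the cells taken. Of the 9 genes above, Ahr (2.28-fold in EOM, a log2 ratio of 0.99, and 0.0135 times in TA), Nrp1 (9.72-fold and 0.543 times), Nid1 (1.74-fold and 0.253 times) and Ptx3 (1.31-fold and 0.0411 times) also went up in EOM and down in TA, but by less than 2-fold in 1 of the muscles.

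The first pattern weighed is the higher level of matrix genes in activated EOM cells, a median log2 ratio of 0.47 over the 82 measured genes of the 3 matrix lists, 64 of them higher. A minority of matrix-rich cells of another type, as the whole cause and without free RNA from them, would leave the median cell alike. At 5000 UMIs the median EOM cell held 29 matrix UMIs and the median TA cell 21, a ratio of 1.38. With 16 against 14 at the 10th percentile of cells and 52 against 30 at the 90th, a part from matrix-rich cells stays open. Free RNA of such cells would raise the median cell too. It was not measured in these libraries, so a minority that sheds RNA is not excluded as the whole cause. Fibroblasts or their RNA would bring Col1a1, Dcn, Lum, Dpt and Col3a1, whose summed difference came to 4.44% of the 468 CPM by which Col1a2 was higher. Col1a1 was itself higher in EOM (11.2 against 2.80 CPM), so a small part from fibroblasts stays open. More differentiating cells in TA, as the whole cause, would leave no difference where EOM cells are not behind. In cells matched on their share of differentiation UMIs in 20 bins the differentiation list was at 0.21 and the matrix median at 0.27 (79 genes, 55 higher, random lists' standard deviation 0.0301). That standard deviation takes no account of matrix genes that move together, so it may be too small a measure. A match within 0.1 of 0 on the differentiation list had been asked for at first and was missed on the side where EOM cells are ahead. A part from differentiation, with a change in the matrix median of -0.20, therefore cannot be told apart from that overshoot. Without cells holding Myog, Mymk or Mymx at 2000 UMIs the matrix median was 0.56 (86 genes, 66 higher). There the differentiation list was at -0.62, so that setting did not match the muscles on differentiation. Each muscle had 1 library per state, so preparation of the library cannot be told apart from the muscle, and a difference between the muscles' cells also stays open, as untested.

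The second pattern is the lower level of cholesterol synthesis genes in quiescent EOM. Cell quality, read from the mitochondrial share, is argued against as the whole cause: among cells matched on that share in 10 bins from 4 to 14%, which take in cells above the 10% limit used elsewhere, the median log2 ratio of the list was -1.09, and between -1.97 and -0.44 in single bins. In the 6 bins up to 10% it was -1.10, and between -1.22 and -0.44. The gap was larger at higher shares: -0.78 at 4 to 5% (33 TA cells), -0.44 at 5 to 6%, -1.22 at 9 to 10% and -1.37 at 13 to 14%. A part from cell quality therefore stays open. Longer handling of TA cells cannot be told apart from muscle with these genes: immediate early and stress genes had a median of -0.0365, with 53.1% of them lower in EOM, which decides neither way. A biological difference between the muscles was not tested and stays open beside library preparation.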

How the results depend on the processing

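A limit of 20% mitochondrial UMIs and the cell state settings at 2000 UMIs were chosen after the data had been seen; the other settings were planned. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers, each having 1 library, which also leaves no replicate to leave out; a model adding muscle and state over the 4 libraries was not fitted. Unless said, the cause was not tested.

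Of 180 counts of genes under other settings 147 stayed within 1.5 times the main count. Of 942 list medians 666 moved by no more than the standard deviation of random lists, 265 moved further and 11 reversed, where a reversal was counted only for medians in the outer 5% of random lists. Of 13057 log2 ratios of named genes 9300 stayed within their counting interval, 3739 did not and 18 reversed, counted only for ratios of at least 2-fold; and of 504 shares 291 stayed within the main interval and 213 did not.

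Expression minimums change how many genes are counted. With 5 CPM, 362 genes were at least 2-fold higher and 219 lower in quiescent EOM than in TA, 220 and 105 in activated EOM, 2423 lower on activation in EOM and 2328 in TA, and 51 higher and 34 lower in EOM in both states. With 100 CPM these were 43 and 42 (quiescent) and 16 and 14 (activated), with 676 higher and 497 lower on activation in EOM, 694 and 492 in TA, and 12 and 4 in both states. With no minimum they were 510 and 315, 309 and 148, 2769 and 3089, and 3128 and 2986. A pseudocount of 10 CPM, which shrinks ratios of low genes, left 97 higher in quiescent EOM, and 62 higher and 28 lower in activated EOM.

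At most 5% mitochondrial UMIs left 46 quiescent TA cells beside 263 of EOM, and with so few cells 596 genes were at least 2-fold higher and 670 lower in quiescent EOM. There the log2 ratio of quiescent EOM to TA was -1.08 for Col1a2, -0.0809 for Col6a2, 2.14 for Runx2 and -0.32 for Ifit3, and that of activation was -1.67 for Col1a2 in TA and -0.00532 for Cdkn1c in EOM. At most 20% gave a median of 0.000322 for ribosomal proteins on activation in EOM.

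TMM factors gave ribosomal proteins a median of -0.0456 in quiescent EOM against TA and 0.39 on activation in EOM. Median-of-ratios factors gave -0.0569 and 0.23, and -0.0162 for G2 and M phase genes in activated EOM against TA.

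Without cells holding Myog, Mymk or Mymx (687 EOM and 215 TA activated cells left) 78 genes were lower in activated EOM; ribosomal proteins had a median of 0.0701 on activation in EOM, and log2 activation ratios were -0.67 for Mef2a and -1.38 for Cdkn1c in EOM and 0.73 for Col1a1 in TA. Read at 2000 UMIs, the count was 78 again, the median 0.0407, and the ratios -0.48 for Mef2a and -1.27 for Cdkn1c. Without cells holding Mki67 or Top2a (793 and 650 left) the medians of EOM against TA were 0.0387 for differentiation genes, -0.0105 for G2 and M phase genes and -0.17 for Notch genes. There the activation ratios in EOM were -0.43 for Creb3l1, -0.85 for Ebf1, -0.94 for Col1a1 and -0.44 for Pdgfrb, and in TA -0.40 for Pold3, -0.31 for Pcolce2 and -0.14 for Id2. Read at 2000 UMIs (2851 and 2281 left), the same setting reversed none of these medians and ratios.

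Shares move with depth by construction. Myog, Mymk or Mymx was found in 45.5% of activated EOM and 55.4% of activated TA cells at 1000 UMIs, in 64.4% and 77.6% at 5000 and in 87.7% and 94.98% without thinning. At least 2 G2 and M phase genes were found in 91.9% and 91.0%, 99.96% and 99.8%, and 99.91% and 99.88%; at 2000 UMIs the share was 97.8% and 97.7%, with 53.2% and 48.8% in quiescent EOM and TA, so that it tells little about division.

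Some settings give no value: a gene that defines a cell state setting has no cells with it there, genes with 3 counts or fewer in both libraries have no ratio, and totals without mitochondrial and ribosomal genes give those lists no median. Depth limits low genes: one with no UMI in quiescent EOM or TA was set at 0.171 or 0.196 CPM, and one with 1 to 3 UMIs has a ratio with a wide counting interval.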

Other observations

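All tests in this part were chosen after the results that prompted them had been seen, and they are hypotheses found and tested on the same libraries.

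Asb4, an imprinted gene, was at 1.37 CPM in quiescent EOM and 16.6 in quiescent TA (0.0826 times, 0.0519 to 0.126), and at 0.35 and 7.34 in activated cells (0.0477 times, 0.0342 to 0.0649). Among mural markers, Vtn, vitronectin, was at 140 and 84.5 CPM in quiescent EOM and TA. In activated EOM and TA it was at 0.0651 and 0.00976 CPM, the latter below the 3-count floor of 0.0293 CPM, so no order is read there. Acta2, smooth muscle actin, was at 268, 99.1, 2027 and 1178 CPM in quiescent EOM, quiescent TA, activated EOM and activated TA. Of the 5 mural markers measured in activated cells, 1 was at least 2-fold lower in EOM.

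A first hypothesis is that regulators of position may keep their muscle difference in culture more often than other genes. Of 12 head, eye-muscle, trunk and limb regulators with 20 CPM or more in any of the 4 libraries and at least 2-fold apart in quiescent cells 10 (83.3%) were so in the same direction in activated cells, and Msc and En1 were not. Among 340 other genes it was 40 (11.8%). With 20 CPM or more asked of a quiescent library it was 7 of 9 regulators (77.8%) and 28 of 281 other genes (9.96%). The share of the 12 regulators lay at percentile 100 of random picks of as many genes, which kept 24.5% on average. These picks were matched on direction and on 3 classes of size only. Regulators very far apart could thus be set beside genes less far apart. Hoxa7, Hoxa9 and Hoxa10, at 7.13, 8.24 and 15.2 CPM in quiescent TA, reached 20 CPM only in activated TA, which favoured their being counted as kept. The percentile therefore cannot separate position from the size of the difference. Both lists hold factors the study may have been built around, so this is not independent evidence.

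A second hypothesis, from H19, Cdkn1c and Mest, is that imprinted genes as a group may be higher in activated EOM cells. The other 32 imprinted genes measured had a median log2 EOM to TA ratio of 0.18 (percentile 99.98 of matched random lists), with 23 of them higher. In quiescent cells it was 0.27 over 33 genes (percentile 99.7), with 25 higher. Nnat, neuronatin, was 12.4-fold (9.64 to 16.3) and the transporter Slc38a4 2.36-fold higher (2.22 to 2.51) in activated EOM. On the lower side, Asb4 was 0.0477 times (0.0342 to 0.0649) and Zdbf2 0.611 times the TA level (0.578 to 0.647). The random lists take no account of members that share a locus and may move together, so the percentile may overstate the support. Library preparation was not separated from muscle in this test.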
